A study of Mus musculus with 864 samples.

How the data were processed

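The measurement was single-cell RNA sequencing of mouse dorsal root ganglion cells. Per the labels, 6 lumbar ganglia (levels 4 to 6) were taken from mice of 6 to 8 weeks, dissociated with enzymes and enriched on Percoll. Cells were picked by hand into plates, 48 per picking over 40 to 60 minutes, and converted to 5′-end tagged libraries with 92 spike-in species at 2500 molecules per well. The table holds 864 wells from 10 plate names, while the series text speaks of 9 plates. It has 25333 rows, of which 1217 are repeat elements, and no spike-in rows.

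The authors mapped the reads with Bowtie (version not given) to mouse build mm9 and deposited RPM, reads scaled to a common total of 1000000, for each gene and well. Per the file headers and the authors' notes no molecular identifiers were counted, so values are shares of reads and not molecules. In 4 of the deposited columns, from 3 empty wells and 1 medium well, all values were whole, and these are treated as a score of unknown scale. Whole reads were recovered for 841 columns from the smallest step of their values and not claimed for 23. Of all recovered values 99.5% were whole within 0.1, and 100% of those up to 100 reads. Reads per well are these recovered totals. Totals for the 23 were taken from the same step and used with the others, though they are not claimed as reads. No coordinates are given, because the reference held here is of another build. A total of 26 row names are bare numbers and were kept as given. Copies of a gene at several loci were summed, leaving 23281 genes, and repeat elements were left out of the gene tests.

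Single-cell wells with 1000 or more genes and 3000 or more reads were kept, 692 of 799. Preparations 1 to 5 kept 213, 45, 176, 184 and 74 cells, and the fewest reads in a single-cell well were 211. Wells labelled as holding more than 1 cell were excluded, and no doublet caller was run. No class annotation was held, so cells were clustered. Values were log-transformed with a pseudocount of 100 RPM and centred on the mean of each session, and genes were split at random (seed 1) into 2 sets. In each set the 600 most variable genes, scaled and limited to 6 SD, gave 15 principal components and a graph of 15 neighbours. Leiden clustering at resolution 2 gave 16 and 17 clusters. A cluster took the class with the largest share of its markers raised by log2 0.5 or more over all other cells (pseudocount 20), with at least 3 raised. It stayed unnamed if its 10 leading genes held more markers of another class, or if it was shallow and they held none of its own. Naming used all markers, from both sets. Each gene was then tested with the labels from the other set. Resolution, naming threshold and marker use were chosen after looking at 6 resolutions, 2 thresholds and 2 uses of the markers, by how many clusters could be named and before any contrast was fitted. An earlier trial used another clustering package. At resolution 1, a cluster of 92 cells stayed unnamed.

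Mean RPM was taken over the cells of each class and preparation with 3 or more cells, which gave 18 pseudobulks. Genes with a mean of 5 RPM or more were fitted as log2(mean RPM + 5) with limma 3.58.1 (trend and robust empirical Bayes), with the preparation as a block for class contrasts (10 residual degrees of freedom). Each class was compared with the mean of the other 3. Because the table holds RPM, limma was kept for the main results, and edgeR 4.0.16 quasi-likelihood fits of summed recovered reads were an alternative. Cells with like classes from both sets, 656 of 692, were 134 NF-like, 165 NP-like, 60 PEP-like and 239 TH-like neurons and 58 other cells. Over all genes 1060 were higher and 749 lower in NF-like, 676 and 784 in NP-like, 351 and 395 in PEP-like, and 685 and 510 in TH-like cells, and the cooling comparison had 113 calls. PEP-like cells reached 3 cells in preparations 1, 3 and 4 only. The sex and cooling comparisons therefore used the unweighted mean over NF-like, NP-like and TH-like cells, a departure from the plan, which had all 4 classes. Sex was fitted with session as a covariate (1 residual degree of freedom) and cooling with sex (2 residual degrees of freedom). All tests were two-sided with a Benjamini-Hochberg adjusted threshold of 0.05. Because animals are not named, p-values do not measure spread between animals. Those of class contrasts measure how class differences varied between preparations, since the preparation is a block. For sex they rest on how the difference varied between sessions A and C, with a spread moderated over all genes.

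Gene lists fixed before the data were examined, 35 in all, were tested in each class contrast with camera at a preset correlation of 0.01 and with an estimated one, and with fry. Lists with 2 or more measured genes made 132 tests. Repeated after seeing the data without the markers that named the neuron classes, 116 pairs of list and class remained. Named genes followed a rule fixed at the same time. For each class they were the 10 largest positive and 5 largest negative differences past the threshold, with a mean of 50 RPM or more on the higher side and the same direction in every preparation, and up to 3 members of each list with the smallest adjusted p. For sex and cooling they were the 10 largest in each direction, with Xist and the Y-linked list. Scn1a in NF-like cells, and Atf3 and Stmn4, were named outside the rule after their values were seen. Some genes that the rule selected, and 1 test that rested on a single gene, are not reported here.

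Cells were compared with control wells by an exact sign-flip permutation test over 10 plates. Shares have Wilson 95% intervals. The procedure was tested on simulated data first. With class labels shuffled within preparations, 15 of 100 genes raised 2-fold and 57 of 98 raised 4-fold were recovered in the NF-like contrast, with 2 false calls. With cells dealt at random between sexes, 67 of 100 genes raised 4-fold and 96 of 100 raised 16-fold were recovered, with 15 false calls.

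Alternatives covered the pseudocount, the filter on low values, quantile normalization, edgeR, blocks and covariates, plates as replicates, 10 or more cells per pseudobulk, all typed neurons, the list tests and leaving out each preparation. Added after seeing the data were resolution 1, a single clustering on all genes, cells with the same class from both sets, 2000 or more genes, thinning to 3000 reads, sessions B and C only, and cells with at most 1000 RPM of globin. Comparisons within a class on published subtypes and RNA per spike-in were planned and not run, since no subtype labels or spike-in values were held. Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and statmod 1.5.0.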

Results

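Individual cells from lumbar dorsal root ganglia of mice, the ganglia that hold the cell bodies of somatic sensory neurons, were picked by hand and sequenced from the 5′ ends of their transcripts. Of 864 wells, 799 held a single cell, 33 held more than one cell, 17 were empty and 15 held medium only. The labels name no animal, so the replicate used here was the preparation, a picking session of one sex. The 5 preparations were session A males (preparation 1), session A females (2), session B males (3), session C males (4) and session C females (5). Picking was at room temperature in sessions A and B and with cooling in session C.

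The single-cell wells held a median of 91121 reads, with a maximum of 31963336, and a median of 3197 genes with a value above 0. After wells with fewer than 1000 genes or 3000 reads were left out, 86.6% of the 799 remained. Median reads per cell in preparations 1 to 5 were 15509, 15597, 198656, 1526080 and 2574690, and median genes were 3006, 2888, 4717.5, 3549 and 3626.5. Depth therefore differed by session. Reads carried no molecular identifiers. Intervals for shares cover the counting error of cells only.

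Control wells asked how much background the libraries carried. Plate medians of single-cell wells exceeded those of empty and medium wells on 10 of 10 plates for genes detected (geometric mean ratio 12.1) and for reads (ratio 276.04). Each had an exact two-sided sign-flip p of 0.00195312, the smallest that 10 plates can give. Counting only genes at 10 RPM or more, cells were higher on 9 of 10 plates (ratio 9.95, exact p = 0.00390625). Control reads ranged from 0.00142% to 53.2% of the cell median by plate, with a median of 0.705%. Transcripts of abundant sensory neuron genes were among the background: Sncg, a synuclein of sensory neurons, had reads in 28 of 32 control wells, Nefm in 15, Calca in 9, Pvalb in 6, Th in 3 and Mrgprd in 1. Mean reads per well were 0.375 in controls against 183.3 in cells for Pvalb, and 0.156 against 614.03 for Th.

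Cells fell into 4 neuron classes named from marker genes: a neurofilament-rich class that was NF-like (19.4% of kept cells), a nonpeptidergic nociceptor class that was NP-like (23.8%), a peptidergic nociceptor class that was PEP-like (60 cells, 8.67%) and a class with tyrosine hydroxylase that was TH-like (34.5%). A further 45 cells were fibroblast-like, a mixed group. Its clusters also raised 8 immune, 7 or 8 endothelial, 6 mural, 6 satellite glia and 4 or 5 Schwann cell markers. Another 13 cells were satellite-glia-like, and 36 had unlike classes from separate sets of genes and were left out of these totals. Each gene was tested with classes made from the other set of genes. Labels from the separate sets were the same for 94.8% of cells (adjusted Rand index 0.916). The classes remain defined from these cells, so the tests below measure how large and how repeatable a difference was, not whether a class exists.

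Shares of picked neurons varied between preparations. TH-like cells made up 41.1% ± 11.8 (SD, n = 5) with a range of 28.9% to 56.9%, NP-like cells 28.2% ± 3.15 (22.8% to 31.03%), NF-like cells 22.8% ± 12.2 (8.62% to 40%) and PEP-like cells 7.85% ± 5.43 (2.22% to 14.1%). In preparation 5, 5 of 58 neurons were NF-like (8.62%, 95% Wilson interval 3.74% to 18.6%), against 18 of 45 in preparation 2 (40%, 27.02% to 54.5%). PEP-like cells numbered 1 of 45 in preparation 2 (2.22%, 0.393% to 11.6%) and made up 14.1% of neurons in preparation 3 (21 cells, 9.41% to 20.6%). Over all single-cell wells in place of typed neurons, TH-like shares were 30.2% ± 3.602 (27.1% to 36.3%). Cells were chosen by hand, so these are shares of picked cells.

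**Figure D1:**
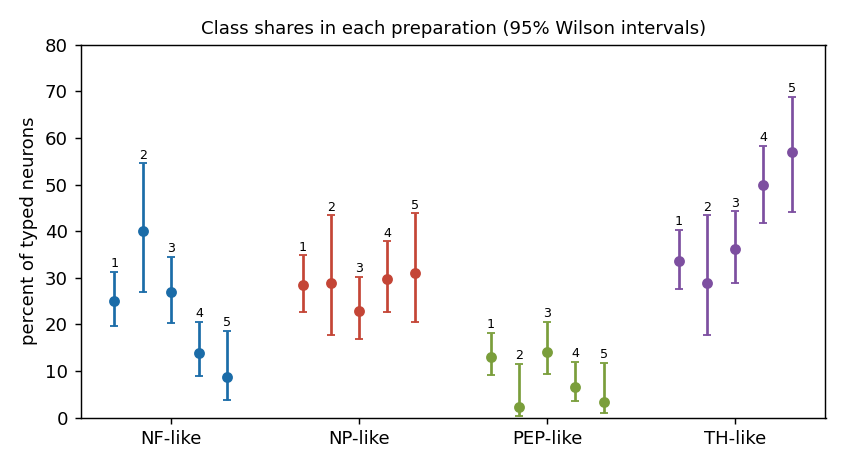
Percent of typed neurons in each class (vertical axis) for preparations 1 to 5, with 95% Wilson intervals as bars. TH-like shares ran from 28.9% in preparation 2 to 56.9% in preparation 5, and NF-like shares from 8.62% in preparation 5 to 40% in preparation 2.

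Class values below are mean RPM over preparations ± SD, with n = 5 preparations for NF-like, NP-like and TH-like cells and n = 3 for PEP-like cells. PEP-like values thus come from male preparations only, while RPM of the other classes set beside them also cover female ones. Each class was set against the mean of the other 3 in 9830 genes. Differences are log2 ± SE with limma p-values adjusted over all genes tested. List p-values come from camera, adjusted over all list and class pairs. Calls kept their side of the threshold with an estimated correlation except where that p is given. The pairs include the marker lists, raised in their own class by construction. Without these and the naming markers, that adjusted p was 0.0975 for TH-like sodium channel genes and 0.0758 for PEP-like inhibitory receptor genes. For NF-like cells it was 0.0975 for GABA-A and glutamate receptor and for ribosomal protein genes, and 0.0929 for Schwann cell genes. It was 0.0644 for NP-like oxidative phosphorylation genes and 0.0915 for TH-like Schwann cell genes. Named genes had their direction in every preparation with the class, with exceptions stated. Directions of the marker genes that named the classes are by construction, and these markers were partly chosen on such cells. For a list call that included naming markers, the adjusted p without these members is also given.

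NF-like cells were set apart by genes of large, fast-conducting axons and by higher levels of mitochondrial energy genes. Beside the naming marker Pvalb, a calcium buffer of proprioceptors (1216 ± 385.97 RPM against 30.4 in the other classes), the calcium sensor gene Vsnl1 stood at 338.2 ± 90.1 RPM against 13.8. The glutamate transporter gene Slc17a7, which encodes VGLUT1, stood at 113.9 ± 30.4 RPM against 2.6. The nociceptor sodium channel genes Scn10a and Scn11a were lower (log2 -5.02 and -5.06). In all, 1809 genes passed, 58.6% of them higher.

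Genes of myelinated fibres and nodes of Ranvier rose together, with 12 of 13 measured members higher and 1 lower over all genes and the same counts adjusted over the list alone (median 2.66, adjusted p = 9.91e-13, or 1.44e-07 without 3 naming markers). Kcna1, a juxtaparanodal potassium channel gene, was at 649.1 ± 95.3 RPM against 70.8 (log2 3.30 ± 0.22, adjusted p = 4.32e-11). Scn8a, which encodes the nodal sodium channel Nav1.6, was higher by 3.14 ± 0.33 (adjusted p = 1e-07). The naming markers on it include Nefh (3.72 ± 0.21) and Spp1, which encodes osteopontin (4.21 ± 0.39). Filament genes diverged: Nefh, Nefm (2.95 ± 0.14) and Nefl (2.16 ± 0.13), all naming markers, were higher while Prph, the filament of small neurons, was lower (-0.81 ± 0.09, adjusted p = 3.61e-07). Of the 5 measured, these were the only members that passed, over all genes and adjusted over the list alone (list adjusted p = 0.000951), and the list call was lost without the naming markers (adjusted p = 0.183).

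Oxidative phosphorylation genes were higher in 66 of 78 measured members and lower in none, or 68 adjusted over the list alone (median 0.81, adjusted p = 4.89e-32). They included Cox4i1, a subunit of cytochrome c oxidase (0.95 ± 0.07), and the ATP synthase subunit genes Atp5g1 (1.46 ± 0.12) and Atp5k (1.09 ± 0.10). Cytosolic ribosomal protein genes were lower in 18 and higher in 1 of 74 members (19 lower and 1 higher adjusted over the list alone; median -0.26, adjusted p = 4.01e-06). Median genes detected were 5305 in NF-like cells and 2812 to 3461 in the other neuron classes.

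Sodium channel genes moved both ways, with 4 of 13 higher and 5 lower (6 and 5 adjusted over the list alone) and did not pass as a list (adjusted p = 0.646). Its median was 0.10 while its mean of -0.28 and its test pointed down. Scn1a, chosen for naming after its values were seen, was at 196.9 ± 39.3 RPM (log2 2.96 ± 0.32). Potassium channel genes had 10 higher and 5 lower of 23 (11 and 5 adjusted over the list alone), with a list adjusted p of 0.0547. Kcnc1, a Kv3 channel gene of fast-spiking neurons, was higher by 3.37 ± 0.38 (adjusted p = 3.66e-07). GABA-A and glutamate receptor genes were higher in 8 of 16 and lower in 1 (10 and 1 adjusted over the list alone; list adjusted p = 0.00757), with Gabrg1 at 71 ± 61.7 RPM against 0.624.

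Of 10 neuropeptide genes 6 were lower in NF-like cells and 0 higher (7 and 0 adjusted over the list alone; list adjusted p = 1.36e-09, or 0.00252 without 7 naming markers and 0.0644 with an estimated correlation as well), among them the naming markers Calca (-4.30 ± 0.52) and Calcb (-2.46 ± 0.16) and the neuromedin gene Nmb (-3.47 ± 0.31). The nociceptor transcription factor genes Prdm12 and Runx1 were lower (-4.48 and -3.53). Mas-related receptor genes were lower in 4 of 5 (5 adjusted over the list alone; list adjusted p = 0.00409), a call lost without the naming markers (adjusted p = 0.133). Itch-associated genes were lower in 7 and higher in 1 of 15 (11 and 2 adjusted over the list alone), and their list call (adjusted p = 0.00036) was lost at an adjusted p of 0.133 with an estimated correlation and 0.0991 without the naming markers. TRP channel genes were lower in 5 of 11 by both adjustments, over all genes and adjusted over the list alone, and their call (adjusted p = 0.0189) was lost at an adjusted p of 0.146 with an estimated correlation and 0.0884 without the naming marker. Axon injury genes were lower in 3 of 11 and higher in 0 by both, over all genes and adjusted over the list alone, and their call (adjusted p = 0.00871) was lost at an adjusted p of 0.211 with an estimated correlation and 0.0656 without the naming marker.

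The calcium-binding gene S100b, also expressed by glia, was at 2777 ± 644.7 RPM in NF-like cells against 265.9 (log2 4.32 ± 0.26, adjusted p = 1.85e-11). Of 9 satellite glia genes 2 passed as higher, S100b and Dbi, by both the adjustment over all genes and that adjusted over the list alone, where 1 more was lower (list adjusted p = 0.859). Myelinating Schwann cell genes were lower in 3 of 4 by both, over all genes and adjusted over the list alone (list adjusted p = 0.00498). Outside the naming markers, 1779 genes passed in this class. The share of genes past the threshold was 18.4%, against 8.91% with cells thinned to 3000 reads and 11.5% in sessions B and C alone.

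NP-like cells were marked by itch-associated genes and by 2 sodium channel genes of small nociceptors. Scn11a, which encodes Nav1.9, was at 845 ± 76.9 RPM against 135.7 in the other classes, and Scn10a, which encodes Nav1.8, was higher by 3.19 ± 0.30. The largest difference was in Tmem233, a transmembrane protein gene, at 1691 ± 1347 RPM against 22.3. Pcp4, a calmodulin regulator gene, was lower (log2 -4.95). In all, 1460 genes passed, 46.3% of them higher.

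Itch-associated genes rose in 13 of 15 measured members and fell in 0, with 14 higher adjusted over the list alone (median 2.92, or 5.37 with edgeR, adjusted p = 8.6e-17, or 4.07e-08 without 7 naming markers). Whether the other members were drawn from earlier work on such cells was not examined, so the call is not independent evidence. Members included Plcb3, a phospholipase of histamine signalling (3.57 ± 0.33), the irritant receptor gene Trpa1 (2.43 ± 0.35), and the naming markers Mrgprx1, a pruritogen receptor gene (2.92 ± 0.33), and Sst, which encodes somatostatin (3.22 ± 0.48, in 4 of 5 preparations). Within the class, Sst stood at 399.2 RPM in a cluster led by Nppb and 4.07 in the other NP-like cells. Mas-related receptor genes were higher in 4 of 5 by both adjustments, over all genes and adjusted over the list alone (list adjusted p = 9.25e-07), with the naming marker Mrgprd at 178.2 ± 50 RPM and Mrgpra2a higher by 3.19 ± 0.37. The Mas-related call was lost without the naming markers (adjusted p = 0.168).

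TRP channel genes were higher in 4 of 11 and lower in 0 (5 higher adjusted over the list alone), with an adjusted p of 0.00135 that became an adjusted p of 0.0596 with an estimated correlation and 0.003 without the naming marker. Trpc6, a receptor-operated channel gene, was higher by 3.22 ± 0.32. The ATP receptor gene P2rx3, a naming marker, was at 529.5 ± 169.9 RPM against 57. Signalling genes among the largest differences were Gna14, a G protein subunit gene (4.61 ± 0.35), Prkca, a protein kinase C gene (4.20 ± 0.39), and the lysophosphatidic acid receptor gene Lpar3, a naming marker (4.42 ± 0.36). Grik1, a kainate receptor gene, was at 551.4 ± 132.5 RPM against 101.05 (adjusted p = 1.55e-09). Neuropeptide genes were higher in 6 of 10 and lower in 2 (6 and 3 adjusted over the list alone; list adjusted p = 0.00647, lost at 0.11 without the naming markers), with Nmb higher by 3.27 ± 0.31.

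Genes of myelinated fibres and nodes were lower in 12 of 13 and higher in 1, by both adjustments, over all genes and adjusted over the list alone (median -1.92, adjusted p = 1.96e-11, or 8.53e-09 without 3 naming markers). Among them, Kcna1 (-2.56 ± 0.22) and Scn1a (-2.94 ± 0.32) were lower. Sodium channel genes as a list were lower in 6 and higher in 2 of 13, the same counts adjusted over the list alone, and the call (adjusted p = 0.0331) was lost at an adjusted p of 0.154 with an estimated correlation. Potassium channel genes were lower in 7 and higher in 2 of 23 (7 and 3 adjusted over the list alone), and the call (adjusted p = 0.0383) was lost at an adjusted p of 0.158 with an estimated correlation. The acid-sensing channel genes Accn3 and Accn2, now named Asic3 and Asic1, were lower (-3.71 ± 0.32 and -3.10 ± 0.38). The neurotrophin receptor gene Ngfr was lower (-2.99 ± 0.25).

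Oxidative phosphorylation genes were lower in 41 of 78 and higher in 0 (49 lower adjusted over the list alone; median -0.40, adjusted p = 5.41e-15), with Atp5k at -0.72 ± 0.10. Ribosomal protein genes were higher in 5 and lower in 1 of 74 (3 and 0 adjusted over the list alone), and their call (adjusted p = 0.00115) was lost at an adjusted p of 0.133 with an estimated correlation. Transmitter synthesis and transport genes were lower in 3 of 6 by both adjustments, over all genes and adjusted over the list alone, and the call (adjusted p = 0.00693) became an adjusted p of 0.0681 with an estimated correlation and 0.186 without the naming markers. Outside the naming markers 1429 genes passed. The share of genes past the threshold was 14.9%, against 6.09% with cells thinned to 3000 reads, 8.06% in sessions B and C alone and 9.72% without preparation 1.

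**Figure D2:**
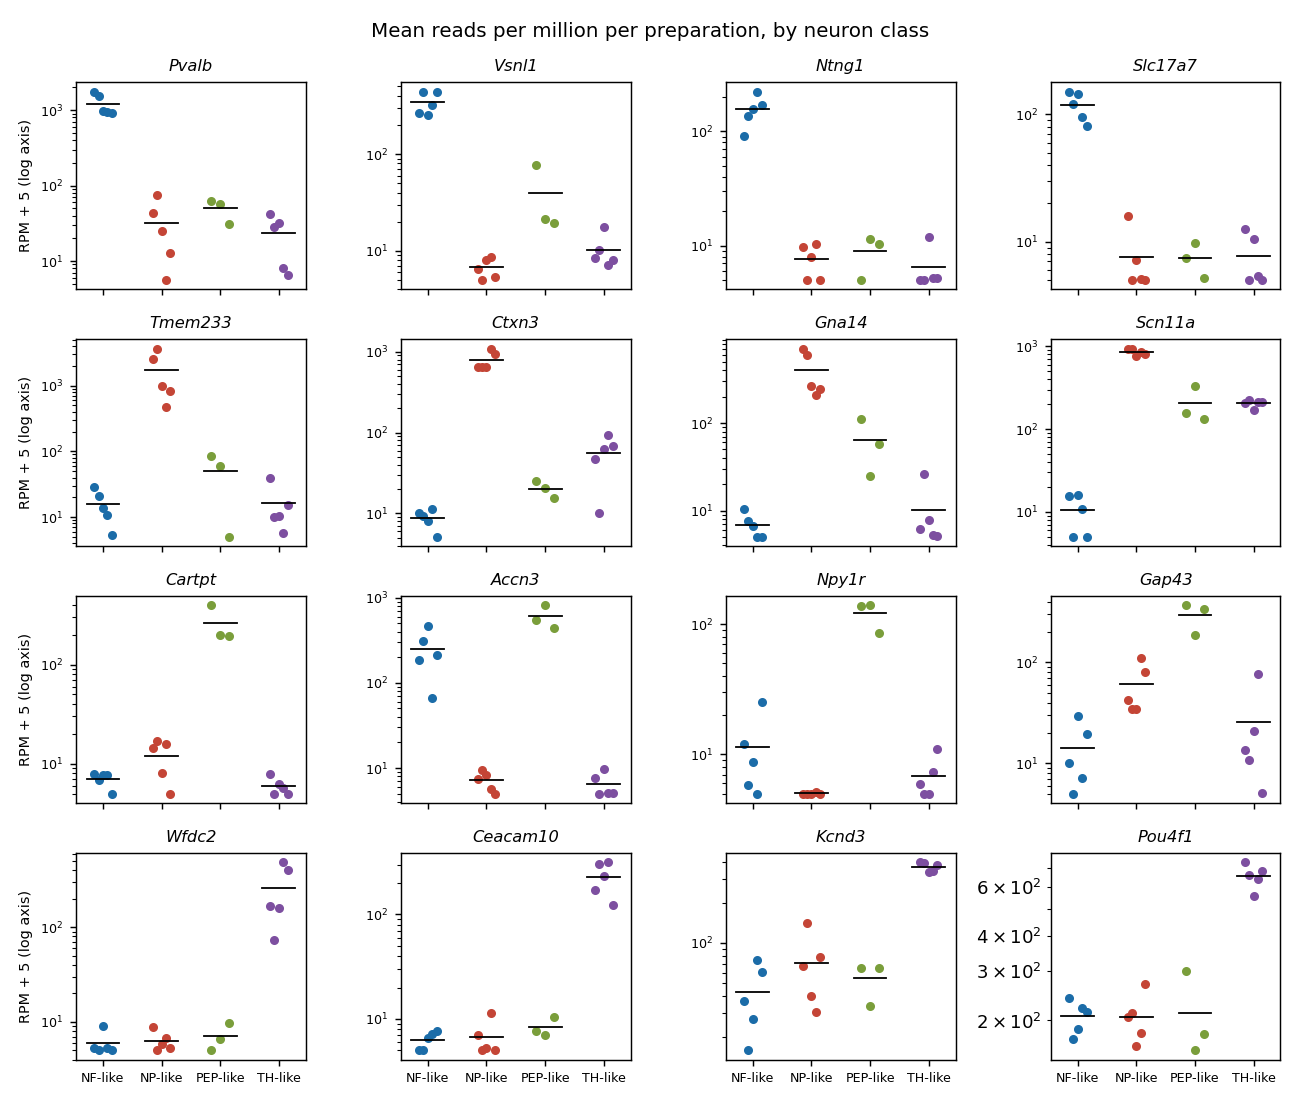
Mean RPM plus 5 on a log axis in each preparation (points) by neuron class, with the mean over preparations as a line, for 16 named genes. Each point is the mean over the cells of a class in 1 preparation. Pvalb in NF-like cells averaged 1216 ± 385.97 RPM and Scn11a in NP-like cells 845 ± 76.9 RPM.

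PEP-like cells combined high neuropeptide expression with higher levels of inhibitory receptor genes. The naming markers Calca, which encodes calcitonin gene-related peptide (6126 ± 2645 RPM against 542.7), and Gal, which encodes galanin (299.2 ± 108.6 RPM), were the highest by log2 difference. Outside the naming markers, Gpx3, an extracellular glutathione peroxidase gene, was at 535.3 ± 402.2 RPM against 11, and the acid-sensing channel gene Accn3 at 599.3 ± 188.8 RPM against 82.4. In all, 7.59% of the 9830 genes passed, 47.1% of them higher.

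Neuropeptide genes were higher in 7 of 10 and lower in 0 (7 and 1 adjusted over the list alone; median 2.91, adjusted p = 2.25e-11). The list held 7 naming markers, without which its adjusted p was 0.00144, or 0.0644 with an estimated correlation as well. Its members included the naming marker Adcyap1, which encodes PACAP (5.05 ± 0.52), and Cartpt, a satiety peptide gene (4.85 ± 0.42), whose call was lost among cells with 2000 or more genes. Inhibitory receptor genes were higher in 3 of 10 and lower in 1 (6 and 2 adjusted over the list alone; list adjusted p = 0.00266). Npy1r, a neuropeptide Y receptor gene, was at 115.9 ± 30.5 RPM against 2.76 (log2 4.24 ± 0.42, adjusted p = 3.69e-07), and the somatostatin receptor gene Sstr2 was higher by 3.58 ± 0.39 (adjusted p = 1.19e-06). Axon injury genes were higher in 4 of 11 and lower in 0 by both adjustments, over all genes and adjusted over the list alone (median 1.11, adjusted p = 2.4e-06, or 0.000914 without the naming marker and 0.214 with an estimated correlation as well). Those that moved are also genes of uninjured peptidergic neurons and growing axons: Gal, the growth-associated gene Gap43 (3.41 ± 0.57), the calcium channel subunit gene Cacna2d1 (2.12 ± 0.26) and Stmn4 (2.18 ± 0.54), while Atf3 stood at -0.12 ± 0.67.

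The growth factor receptor genes Kit (5.10 ± 0.40) and Gfra3, the artemin receptor (4.53 ± 0.52), and the capsaicin receptor gene Trpv1 (3.38 ± 0.53) were all naming markers. Neurotrophic factor receptor genes did not pass as a list, with 3 of 8 higher and 2 lower (3 and 3 adjusted over the list alone; adjusted p = 0.676). Its median was -0.83, or 0.12 with edgeR, while its mean was 0.43 and its test pointed up. Kcnk3 and Kcnk2, which encode background potassium channels, were higher by 4.28 ± 0.58 and 2.51 ± 0.40. Atp2b4, a plasma membrane calcium pump gene, was at 330.98 ± 169.03 RPM against 12.8. Trpm8, the cold and menthol receptor gene, was at 47.4 ± 69.9 RPM and higher in 2 of 3 preparations. Among lower genes were Acpp, a phosphatase of nonpeptidergic neurons (-3.07 ± 0.36), the sodium pump regulator gene Fxyd2 (-3.30 ± 0.21) and Rasgrp1 (-3.19 ± 0.41). GABA-A and glutamate receptor genes were lower in 3 of 16 and higher in 0 (4 lower adjusted over the list alone), and the call (adjusted p = 0.00941) became an adjusted p of 0.0541 with an estimated correlation.

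Oxidative phosphorylation genes were lower in 13 of 78 (18 adjusted over the list alone; median -0.31 beside -0.16 for all genes, and -0.084 with edgeR), and the call (adjusted p = 1.4e-06) was lost at an adjusted p of 0.119 with an estimated correlation. Pan-neuronal genes were higher in 3 and lower in 2 of 13 (5 and 2 adjusted over the list alone), and their call (adjusted p = 0.0445) became an adjusted p of 0.111 with an estimated correlation. The class rested on preparations 1, 3 and 4, all male, and without 1 of them 3.67%, 3.46% or 3.23% of genes passed. The share was 3.57% with edgeR, which moved the median over all genes to -0.039, 2.64% with cells thinned to 3000 reads, 4.83% without the preparation block, 4.73% in sessions B and C and 16.8% with plates as replicates.

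TH-like cells had higher levels of sodium channel genes and lower levels of neuropeptide genes than the mean of the other classes. Neuropeptide genes were lower still in NF-like cells, with a mean log2 difference over the list of -2.24 against -1.54 in TH-like cells. Beside the naming markers Th, which encodes tyrosine hydroxylase (2375 ± 1704 RPM against 42.2), and Fam19a4, a secreted protein gene (599.9 ± 297.7 RPM), the secreted protein gene Wfdc2 was at 253.6 ± 177.9 RPM against 1.48. Kcnd3, which encodes the A-type potassium channel Kv4.3, was at 366.3 ± 27.8 RPM against 51.2. The granin gene Scg2 was lower (log2 -4.29). In all, 1195 genes passed, 57.3% of them higher.

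Sodium channel genes were higher in 5 of 13 and lower in 0 (6 higher adjusted over the list alone; median 0.75, adjusted p = 0.00113). Scn9a, which encodes Nav1.7, was at 658.6 ± 177.5 RPM against 298.6 (log2 1.11 ± 0.14, adjusted p = 4.5e-06). The auxiliary subunit genes Scn3b and Scn2b were higher by 2.47 ± 0.37 and 2.18 ± 0.41, the latter call being lost in thinned cells. Calcium channel genes were higher in 4 of 10 and lower in 0 (4 and 1 adjusted over the list alone; list adjusted p = 0.0555). They included the T-type channel genes Cacna1i (3.10 ± 0.35) and Cacna1h (2.04 ± 0.37), which carry low-threshold currents. Cacna1h was a naming marker of NF-like and not of TH-like cells, and all 13 such NF markers were higher in NF-like cells. Potassium channel genes moved both ways, with 3 higher and 5 lower of 23 (6 and 5 adjusted over the list alone). Their median was 0.10, their mean -0.06 and the list adjusted p 0.663, with the Kv3.4 gene Kcnc4 at -3.42 ± 0.32.

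Neuropeptide genes were lower in 5 of 10 and higher in 0 (6 lower adjusted over the list alone; list adjusted p = 1.48e-06, or 0.00564 without 7 naming markers and 0.0854 with an estimated correlation as well). Calca, a naming marker, was lower (-3.92 ± 0.52, a call lost with edgeR), as was Pcsk2, a prohormone convertase gene (-3.80 ± 0.42). Neurofilament genes were lower in 3 of 5 and higher in 0 by both adjustments, over all genes and adjusted over the list alone (median -1.32, adjusted p = 1.23e-05), with Nefh at -2.76 ± 0.21. All 3 were naming markers, and without them the call was lost (adjusted p = 0.781). The vesicular glutamate transporter gene Slc17a8, which encodes VGLUT3, the mechanosensitive channel gene Fam38b, now named Piezo2, and the ADP receptor gene P2ry1 were naming markers, higher by 3.65 ± 0.36, 1.90 ± 0.15 and 3.64 ± 0.32. Sensory transcription factor genes had 7 of 20 higher and 3 lower (8 and 5 adjusted over the list alone; list adjusted p = 0.123), with Pou4f1, a POU-domain factor of sensory neurons, at 650.7 ± 65.9 RPM against 203.3. The GDNF family receptor gene Ret was higher by 1.505 ± 0.18.

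Several list calls rested on the preset correlation. Axon injury genes were lower in 5 of 11 by both adjustments, over all genes and adjusted over the list alone, with an adjusted p of 0.000791 and an adjusted p of 0.122 with an estimated correlation and 0.00857 without the naming marker. Itch-associated genes were lower in 4 of 15 (6 adjusted over the list alone), with an adjusted p of 7.19e-06 and an adjusted p of 0.0686 with an estimated correlation and 0.0146 without the naming markers. TRP channel genes were lower in 4 of 11, the same count adjusted over the list alone, with an adjusted p of 0.0335 and an adjusted p of 0.172 with an estimated correlation and 0.15 without the naming marker. Mas-related receptor genes were lower in 2 of 5 (4 lower and 1 higher adjusted over the list alone), with an adjusted p of 0.0212 and an adjusted p of 0.0742 with an estimated correlation and 0.733 without the naming markers. Pan-neuronal genes were lower in 5 and higher in 1 of 13, the same counts adjusted over the list alone, with an adjusted p of 0.0388 and an adjusted p of 0.104 with an estimated correlation. Transmitter genes were higher in 2 and lower in 1 of 6, the same counts adjusted over the list alone, with an adjusted p of 0.0422 and an adjusted p of 0.146 with an estimated correlation and 0.804 without the naming markers.

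The myelin genes Mbp and Pmp22 were higher in TH-like cells. Mbp, which encodes myelin basic protein, was at 303.2 ± 89.1 RPM against 32.1 (log2 3.57 ± 0.41, adjusted p = 8.55e-07), and Pmp22 was higher by 1.93 ± 0.17 (adjusted p = 1.7e-08). These were the 2 of 4 Schwann cell genes that passed, by both adjustments, over all genes and adjusted over the list alone (list adjusted p = 0.00409). Fibroblast, endothelial, mural and erythroid lists did not pass as lists in any of the 4 classes, with the lowest adjusted p, 0.0844, for endothelial genes in NP-like cells. Outside the naming markers, 1167 genes passed in TH-like cells. The share of genes past the threshold was 12.2%. It was 4.62% with cells thinned to 3000 reads, which moved the median over all genes from 0.063 to 0.20, 5.33% in sessions B and C alone, and 7.45% or 8.09% without preparation 1 or 3.

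Females differed from males in the sex-linked transcripts Xist and Ddx3y, which also served as a check of the labels. Xist, the RNA that silences an X chromosome, was at 53.5 ± 19.7 RPM (SD, n = 2) in females and 0.204 ± 0.176 (n = 3) in males. The Y-linked helicase gene Ddx3y was at 2.23 ± 0.171 RPM in females and 36 ± 7.06 in males. Of 9710 genes, 9 passed with limma, 2 higher and 7 lower in females, and 4.39% had an unadjusted p under 0.05. With cells dealt at random between the sexes, the same fit gave 15 false calls. These came beside genes raised 4-fold and 16-fold by design, of which 67 of 100 and 96 of 100 were recovered. Such true calls loosen the adjusted threshold, and dealing removes the spread between sessions, so 15 is no reference for the 9.

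The log2 difference was 3.46 ± 0.57 for Xist (adjusted p = 8.26e-06) and -2.62 ± 0.53 for Ddx3y (adjusted p = 0.00228). Each had no overlap between the sexes, and all 5 preparations matched their labels. The Y-linked translation factor gene Eif2s3y (-2.08, adjusted p = 0.201) and Uty, a Y-linked demethylase gene listed at 0 in both female preparations (adjusted p = 1), did not pass over all genes. All 3 Y-linked genes tested were lower in females adjusted over the list alone. The other 7 genes that passed are not told apart from false calls here. Among them, Lrrc47 was higher by 1.76 ± 0.39 without overlap. Of all genes tested, 18.2% had no overlap between the sexes, where chance gives 20% for exchangeable preparations. Gapvd1, an endosomal trafficking gene (-2.32), and Fabp7, a fatty acid binding protein gene of satellite glia (-2.53), were lower without overlap. Apoe, an apolipoprotein gene of glia (-1.57), Id3 (-1.48), Fxyd7 (-1.41) and the mitochondrial ribosomal RNA gene mt-Rnr2 (-2.13) were lower with overlapping values. Fabp7 and Apoe were the 2 of 8 satellite glia genes that passed, by both adjustments, over all genes and adjusted over the list alone. Adjusted over the list alone, neuropeptide genes were lower in females in 3 of 8 (median -0.50), PEP markers in 2 of 7 and itch-associated genes in 2 of 15. Erythroid genes were higher in 2 of 2 (median 1.03). None of these passed over all genes.

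Within session A the Xist values were 0.301 RPM in males and 67.4 in females, and within session C they were 0 and 39.5; session B held males only. The fit had 1 residual degree of freedom and, with session as a covariate, took the sex difference from sessions A and C only. The count was 0 without the session covariate, 0 without a filter on low values, 1 in thinned cells and 16 among cells with 2000 or more genes.

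Cooling during picking coincided with session C, so the comparison measures everything that differed between that session and the others. Under cooling the haemoglobin genes Hbb-b2 and Hba-a2 and the ribosomal stalk gene Rplp2 were higher, the last at 2862 ± 199.2 RPM (SD, n = 2) against 352.04 ± 59.3 (n = 3). The immediate early gene Fos, which is induced by neuronal activity and stress, was at 80.2 ± 11.7 RPM against 12.5 ± 10.7. Enpep, an aminopeptidase gene, was at 0.00584 ± 0.00826 RPM against 197.6 ± 109.9. Of 9710 genes, 1.16% passed, 33 higher and 80 lower.

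The globin differences were 6.89 ± 0.78 for Beta-s, 6.61 ± 0.75 for Hba-a2 (adjusted p = 0.0191) and 5.58 ± 0.57 for Hbb-b2 (adjusted p = 0.00293). The latter are the 2 erythroid genes measured, higher over all genes and adjusted over the list alone. Few cells held most of the signal: summed globin averaged 1065 RPM in preparation 4 and 10634 in preparation 5, with medians of 2.04 and 1.60, and the 3 highest cells held 62.8% and 90.6% of it. Low values were widespread, with globin reads in 68.8% and 87.9% of neurons of these deeply sequenced preparations, against 6.67% to 26.2% in the others. Without cells above 1000 RPM of globin, an alternative added after seeing the data, 70 genes passed, Hba-a2 turned to -0.34, and Fos, at 2.31, no longer passed (adjusted p = 0.0540).

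Rplp2 was higher by 2.97 ± 0.30 (adjusted p = 0.00206) and Fos by 2.57 ± 0.44 (adjusted p = 0.0228). Hes1, a Notch target gene (2.66), Sparc, a matrix protein gene of glia and fibroblasts (2.91), and Ifitm3, an interferon-induced gene (2.42), were also higher. Fibroblast genes, of which 0 of 6 passed over all genes, were higher in 4 adjusted over the list alone (median 1.82). Satellite glia genes were higher in 1 of 8, or 2 adjusted over the list alone (median 1.06). Axon injury genes were higher in 1 of 10, or 6 adjusted over the list alone (median 0.95), and immediate early and heat shock genes in 1 of 21, or 2 adjusted over the list alone (median 0.50). Ribosomal protein genes were higher in 2 and lower in 1 of 74, or 10 and 4 adjusted over the list alone, and oxidative phosphorylation genes higher in 1 of 78, or 3 adjusted over the list alone. Acid-sensing and mechanosensing channel genes, of which 0 of 8 passed over all genes, were lower in 3 and higher in 0 adjusted over the list alone (median -0.36). Pan-neuronal genes, of which 0 of 13 passed over all genes, were higher in 3 and lower in 1 adjusted over the list alone (median 0.37). Apart from the erythroid genes above, each other list had at most 1 gene in either direction by both adjustments.

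Lower under cooling were Enpep (-5.10 ± 0.41, adjusted p = 0.000743), Fxyd7, a sodium pump regulator gene (-4.07), and Arhgef11, a guanine nucleotide exchange factor gene (-3.70). Noncoding transcripts among them were Mir690 (-3.57) and Snhg11, a small nucleolar RNA host gene (-3.46, 149.2 ± 20.8 RPM against 1799 ± 891). Rbm11, a splicing regulator gene (-3.19), Akap8l (-3.19) and Strn4 (-3.14) were also lower. Xist (-0.35) and Ddx3y (0.03) did not pass.

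All genes that passed had no overlap between cooled and room temperature preparations, as had 35.3% of all genes tested. Chance gives 20% for exchangeable preparations, which these are not, since both cooled ones came from session C. Repeat-element values averaged 236.6 RPM in session A and 645.6 in session B and were 0 in all single-cell wells of session C, and the origin of this difference was not tested. Clustering of TH-like cells followed session, with the largest cluster in 1 set of genes holding 40.5% of those of session A, 81.4% of session B and 57.4% of session C, each a different cluster. The largest NP-like cluster was the same in sessions A and B and another in session C, where it held 47.5% of these cells, or 49.2% in the other set of genes. The largest NF-like cluster of session C was that of session A in 1 set and that of session B in the other. The comparison therefore does not separate cooling from the make-up of its classes. Only the largest PEP-like cluster, of a class outside this comparison, was the same in all 3 sessions. Without preparation 2 the limma count was 0, with 10.0% of genes at an unadjusted p under 0.05, and preparation 5 was then the only female one. Without preparation 1 the count was 54, and without 3 the share of genes past the threshold was 6.73%. Without preparation 4 or 5 only 1 cooled preparation was left, so its spread could not be measured. The count was 0 without a filter on low values and 56 with a pseudocount of 20 RPM, and the share was 1.77% over all typed neurons and 5.22% with plates as replicates.

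**Figure D3:**
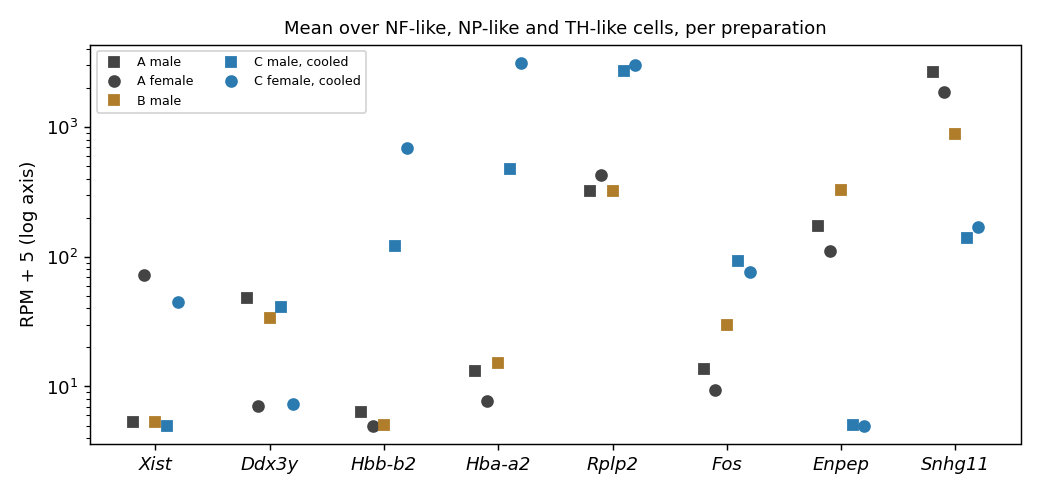
Mean RPM plus 5 on a log axis in each of the 5 preparations for 8 genes, averaged over NF-like, NP-like and TH-like cells; colour marks the session and shape the sex. Rplp2 averaged 2862 ± 199.2 RPM in the cooled preparations and 352.04 ± 59.3 at room temperature.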

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

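Chosen after the results were seen were the tests of depth, of mapping or annotation, of emptied rows and of non-neuronal RNA for the lower genes under cooling, the glial test, and the exchanges of class labels; the tests of non-neuronal RNA for the higher genes, of globin in the suspension and of the depth of energy genes were written before. Exchanging class labels within preparations decides nothing about chance, because the classes were drawn from the expression of these cells: 1 of 100 arrangements, the real one, gave as many genes for each class. The real labels gave 18.4% of genes for NF-like, 14.9% for NP-like, 7.59% for PEP-like and 12.2% for TH-like cells, and the highest of the others gave 0.0916%, 3.63%, 1.61% and 1.66%.

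The first pattern was the 1.16% of genes that differed in the cooled session, globins among them. In thinned cells 98.2% of them kept their direction and an unadjusted p under 0.05. Thinning keeps the expected share of each gene in a cell, and the genes were picked in the same data. Depth, which differed by session, is therefore left open. For the 80 lower genes, emptied rows would leave no reads in session C, which held for 1.25% (1 of 80), and dilution by RNA of other cells would lower genes of all neurons alike. The median of 13 pan-neuronal genes was 0.373 and the lowest of them -0.94, against a median of -2.15 for the lower genes. Open for the 33 higher genes is RNA from non-neuronal cells, since 36.4% (12 of 33) were at least 2 times higher in such cells of session C. Globin free in the suspension may contribute. Control wells of that session averaged 2273 RPM (8 of 16 with reads, up to 15716) beside 3897 in neurons. These RPM are unlike in depth, with plate medians of 11 to 5133 reads in its control wells and 386087 or more in its single-cell wells. Few reads can thus make a high RPM in a control well, and few cells held most of the neuron signal. A difference in mapping or annotation (399.5 RPM of repeat elements in sessions A and B, 0 in C), the session itself and cooling cannot be told apart, because cooling was used in session C only.

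The second pattern was glial genes in neuron classes. Satellite glia in the wells would bring their abundant transcripts, but the median difference of 4 such genes in NF-like cells was -0.22 against 4.32 for S100b. In 13 satellite-glia-like cells Apoe averaged 24919 RPM and S100b 1014, while in NF-like cells they averaged 153.03 and 2724. RNA from Schwann cells is not weighed here as a source of Mbp and Pmp22 in TH-like cells. Expression by the neurons themselves may account for S100b, a hypothesis found and tested on the same data and not tested further.

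The third pattern was the higher oxidative phosphorylation genes in NF-like cells, which also had the most genes detected. The median over 78 genes was 0.79 in thinned cells and 0.81 before. Thinning keeps the expected share of each gene in a cell, so these values do not decide on depth as a cause. A greater share of energy-metabolism transcripts in these neurons remains a hypothesis. Cell size was not measured here, and other technical explanations were not tested.

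A preparation stood far from the other 4 in 10.7% of gene and class groups (24 in all), where chance gives about 1 in 20. In 15 of these the other preparations were all under 2 RPM, where any value above 0 stands out, so the excess is not read as a difference between preparations. In NF-like cells preparation 5 was low for Faim2 (175.3 RPM, others 339.9 to 429.07) and Cd55 (15.4, others 43.2 to 59.8). Preparation 2 was high for Trpv1 (3.20 RPM), preparation 3 for Mrgprx1 (0.0436), Sstr2 (0.0128) and Slc17a8 (2.57), and preparation 4 for Mal (3.54). In NP-like cells preparation 3 was high for Gm765 (1084 RPM, others 216.2 to 324.9) and Sstr2 (2.05). Preparation 1 was high for Kcnk3 (0.988 RPM) and Accn2 (5.57), preparation 2 for P2rx6 (4.02), and preparation 4 for Npy1r (0.111) and Kit (5.36). Preparation 2 was low for Tmem63a (8.14 RPM, others 23.6 to 33.01) and preparation 5 for Egfl7 (0.0463, others 16.2 to 26.99). In TH-like cells preparation 2 was low for Cacna1h (41.3 RPM, others 80.4 to 96.0) and high for Mbp (459.999, others 247.9 to 284.5) and Gal (6.90), and preparation 5 was low for Bhlha9 (67.6, others 164.9 to 200.003). Preparation 3 was high for Rpl4 (21720 RPM, others 630.2 to 1721), Trpv1 (0.414), Trpm3 (1.06) and Kcnk18 (0.509).

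Class-specific differences, tested with limma interaction terms, differed for 5 genes. Between cooled and room temperature picking, the difference in NF-like cells against the other classes was -2.50 for Cd9, 0.85 for Fxyd2 and -3.56 for Id3, each with an adjusted p of 0.00394. In NP-like cells it was -2.37 for Pcp4 (adjusted p = 0.0416). The largest NP-like cluster of session C was another than that of sessions A and B, and the largest NF-like clusters also varied by session. A change in the make-up of these classes is therefore not told apart from a response to cooling. Between females and males, Pcsk2 in TH-like cells differed by -2.90 (adjusted p = 0.000447).

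Some data were not used by the comparisons. Wells with more than 1 cell had a median of 3232 genes detected, where control wells had a median of 418.5 and a maximum of 1865. Repeat elements averaged 230.99 RPM over single-cell wells, against 0 in empty wells and 160.7 in medium wells. Kinds of well were spread unequally over plates and sessions, and session C single-cell wells were all at 0. These means therefore do not rank the kinds of well.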

How the results depend on the processing

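Tests on resolution 1, a single clustering, like classes from both gene sets, 2000 or more genes, thinned cells, sessions B and C, globin and lists without naming markers were chosen only after the data were seen. Named genes kept their direction and side of the threshold in 95.9% of checks for NF-like, 93.9% for NP-like, 87.6% for PEP-like and 92.4% for TH-like cells. The others in these classes were weaker, apart from 1 reversed in NP-like and 2 in PEP-like cells. For sex 61.1% of checks were kept and 38.3% were weaker. For cooling 74.3% were kept, 23.7% were weaker and 2.01% reversed.

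With cells thinned to 3000 reads, which leaves fewer reads, 8.91% of genes passed for NF-like, 6.09% for NP-like, 2.64% for PEP-like and 4.62% for TH-like cells, and 1 gene for sex. Sessions B and C alone gave 11.5%, 8.06%, 4.73% and 5.33%. PEP-like cells gave 3.57% with edgeR, 4.83% without the block and 16.8% with plates as replicates. Without a filter, which adds genes to those tested, the shares for the 4 classes in the same order were 8.87%, 6.25%, 2.91% and 5.04%. Leaving out each preparation gave 13.5% to 17.03% for NF-like, 9.72% to 13.3% for NP-like, 3.23% to 10.1% for PEP-like and 7.45% to 10.3% for TH-like cells.

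The sex count was 16 with 2000 or more genes, 5 with like classes from both gene sets, 3 at resolution 1, 3 with a filter of 20 RPM, 15 over all typed neurons and 2 with plates. It was 0 with limma without the session covariate (3.21% unadjusted) and 0 without a filter (7.12% unadjusted). Leaving out preparation 3 gave 9. That preparation is all of session B, so the session covariate fits it exactly, and leaving it out could hardly change the sex result. Without any other preparation no residual degree of freedom was left. The cooling share was 0.722% without globin-rich cells, 1.77% over all typed neurons, 5.22% with plates, 0.577% with a pseudocount of 20 RPM, 2.73% of fewer genes with a filter of 20 RPM and 0 with limma without a filter (9.21% unadjusted). Leaving out preparation 1, 2 or 3 gave 0 to 6.73%.

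Reversed values were Pmp22 in NP-like cells at resolution 1 (0.24) and, with edgeR in PEP-like cells, Nefl (0.42) and Rpl22 (-0.067). Under cooling they were Hba-a2 without globin-rich cells (-0.34), Ddx3y in thinned cells (-0.083), with 2000 or more genes (-0.069), without the sex covariate (-0.38) and with quantile normalization (-0.087), Uty in thinned cells (0.042) and Xist without the sex covariate (0.23). Leaving out each preparation gave -0.0902 to 0.161 for Ddx3y and -0.845 to 0.00458 for Eif2s3y.

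Lists past the threshold were 38.6% of those tested, against 24.2% with an estimated correlation. Fry, which tests a list against no change where camera tests it against the other genes, asks another question, and 54.5% passed its directional and 80.3% its mixed test. With fry's directional test the direction was opposite for transmitter (adjusted p = 0.189) and pan-neuronal genes (0.0551) in NF-like cells, and for neurotrophic receptor (0.893), pan-neuronal (0.186), Schwann cell (0.746) and PEP marker genes (0.796) in NP-like cells. The same held for potassium channel (0.936), filament (0.893), transmitter (0.258), ribosomal (0.843) and immediate early genes (0.968) in PEP-like cells, and for purinergic (0.0239) and immediate early genes (0.870) in TH-like cells. Without the naming markers 18.1% of the remaining lists passed, against 31.9% of the same lists with them. The direction turned for filament (adjusted p = 0.183) and transmitter genes (0.776) in NF-like, neurotrophic receptor (0.695) and filament genes (0.121) in NP-like, Mas-related (0.872), purinergic (0.976) and transcription factor genes (0.704) in PEP-like, and filament (0.781) and transmitter genes (0.804) in TH-like cells. The NP-like share was 21.5% of all single-cell wells. Apart from the thinning, the cause was not tested.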

Other observations

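All values here were chosen after the data were seen. Within the NF-like class, a cluster led by Pvalb (45 to 46 cells in 4 preparations) differed from the other NF-like cells in 5.28% of 9388 genes with limma, 33.5% of them higher. Pvalb stood at 3490 RPM against 177.7 (log2 4.34), and Spp1 at 848 against 52.2 (4.29). Higher with it were Wls, a Wnt secretion gene (4.76), Accn2, an acid-sensing channel gene (4.73), and Whrn, a scaffold gene of hair-cell stereocilia (3.71). The serotonin receptor gene Htr3a (-4.61) and the peptide precursor gene Vgf (-4.66) were lower.

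Within the NP-like class, a cluster led by Nppb (35 to 39 cells in 4 preparations) differed in 1.18% of 9157 genes, 51 higher and 57 lower. Nppb, which encodes a natriuretic peptide of itch neurons, stood at 386.7 RPM against 1.15 (log2 5.80). The peptide genes Nts (5.52) and Sst (5.28), the pruritogen receptor gene Mrgpra3 (5.14) and the cytokine receptor gene Osmr (3.86) were higher. Grik1 (-5.09), Lpar3 (-5.05) and Gfra2 (-5.00) were lower. Clusters were drawn from the same expression values, and 5 such clusters were fitted, of which these 2 were reported.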
